A study of Mus musculus with 22 samples.

How the data were processed

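Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on mouse embryonic stem cells grown in serum with LIF. Per the labels, the series holds 22 samples in 12 groups. Of these, 14 libraries, 2 per group, stand behind the 7 deposited peak lists analysed here. Those are MTF2, EZH2, H3K27me3 and H3K4me3 in wild-type E14 cells, and EZH2, H3K27me3 and H3K4me3 in cells homozygous for a gene trap in Mtf2. The other 8 libraries were not analysed here. They are the input, Jarid2 in wild-type and gene-trap cells, and MTF2 in Jarid2 knockout and Eed knockout cells. No MTF2 list from gene-trap cells was analysed, so the loss of MTF2 itself could not be checked from the peak lists. The labels give no parental line for the gene-trap cells, so genotype is not separated from line background.

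Per the labels, libraries were made with a Kapa kit and read on a NextSeq in reads of 75 bases. Per the submitters' processing notes, the tools were CASAVA, BWA 0.7.10-r789 and MACS2 2.7, and the genome build was mm10 (GRCm38). The role and order of each tool are not given in those notes. The words MAnorm and unbiased appear in the names of the deposited lists only, and the sources used here do not say what was done under those names. The same holds for the threshold, the control and the way in which the libraries of a group were combined. In each deposited list the values are the chromosome, start and end of a region in bp, without a height, score, fold enrichment or p-value. Starts were counted from 0 in the lists and were converted to positions counted from 1. All region ends lay within the chromosome lengths of GRCm38.

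The lists give no read counts, so the depth of each library is unknown, and a peak missing from a list may reflect its depth or its threshold as well as binding. Per the labels both libraries of a group name the same list, which was read as made from both. The spread between replicates could therefore not be measured, and no test compared cultures. The unit of every test was the peak, the promoter or the gene. Neighbouring regions are not independent cultures, and p-values and intervals cover counting error over regions only. Shares are given with exact Clopper-Pearson 95% intervals.

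A wild-type peak was called kept when a peak of the gene-trap list for the same antibody overlapped it by at least 1 bp, and lost otherwise. A gene-trap peak that overlapped no wild-type peak was called gained. The promoter of a protein-coding gene was the window within 1 kb on either side of any of its transcription start sites (TSS) in the basic set of GENCODE M21, which holds 21827 such genes. A gene had a mark when a peak touched this window, and kept it when a gene-trap peak of that mark touched the window too. It gained a mark when only gene-trap peaks touched the window, and such a peak may overlap a wild-type peak outside it. Widths given for a gene are those of the widest such peak, so a gene-trap width can be less than all that is left of the wild-type peak. Differences between shares were tested with 2-sided Fisher exact tests, and differences between medians with 2-sided permutation tests of 100000 resamples, for which the smallest p is 1e-05. Tests over gene lists were Fisher exact tests (their p is written as adjusted exact p), adjusted by the Benjamini-Hochberg method over the lists tested for a mark, with a threshold of 0.05. Tests within strata of width or CpG density used the Mantel-Haenszel odds ratio or permuted within strata. The differences given for such permutations are between means, averaged over strata, and not between medians. CpG and GCG (on either strand) were counted per 100 bp in the central 1 kb of each peak, in the GRCm38 sequence.

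The comparisons, their tests, the gene lists and most alternatives were fixed before the data were examined. The 14 gene lists were Hox clusters, endoderm regulators, mesoderm and heart regulators, neural regulators, signalling ligands and inhibitors, cell cycle inhibitors, neuronal channels and receptors, pluripotency, housekeeping, germline genes, imprinted genes, extracellular matrix and epithelial genes, PRC2 and partners, and PRC1 components. Together they hold 434 genes, and 1 symbol was not in the annotation. A list was tested for a mark when at least 3 of its genes had a wild-type peak. That gave 12 lists for EZH2 and for H3K27me3 and 14 for H3K4me3.

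Named genes followed a rule. For each mark and list tested, the 2 kept and the 2 lost members with the widest wild-type peak were taken. Outside the lists, the 5 kept, 5 lost and 5 gained genes with the widest peak were taken, passing over predicted genes. List members that gained a mark were taken as well, which the rule as first written did not include. For MTF2 in wild-type cells, the 3 members with the widest peak were taken per list. Mtf2, Ezh2, Eed, Suz12, Jarid2, Phf1 and Phf19 were always reported. The values of 3 genes that this rule takes are not reported here. Genes named outside this rule are said to be chosen after their values were seen.

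Alternatives changed the overlap that counts as shared (50% of the shorter peak, or a distance of 1 kb), the minimum width (500 bp), merging of peaks closer than 1 kb, chromosomes X and Y, bases in place of peaks, the promoter window (2.5 kb, or the TSS inside the peak), genes that share a peak, and width (3 equal classes, or above the median). For sequence, they were the whole peak and peaks at promoters. Alternatives chosen after seeing the data left out each chromosome in turn and took a mutant peak anywhere in the wild-type peak as kept. They also matched lists and sequence within 5 equal classes of width, used the densest 1 kb of each peak by CpG, used 500 bp on either side of the TSS, and matched gain of H3K4me3 within 5 classes of CpG density. Further tests in the closing section counted 75-base sequences that occur more than once in the genome, read every 25 bp, and joined peaks closer than 50 kb into regions. A region was called repeated when over 50% of these sequences were. Gained peaks were also counted in regions with over 40%. H3K4me3 length was summed within 10 kb of the most upstream TSS of each gene, and width matching used 20 bins and 100000 draws.

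The code was tested on simulated data. All 758 kept and 60 gained peaks planted in a simulated list were recovered, and bedtools 2.31.1 and the code used here both counted 5959 MTF2 peaks that overlap EZH2 peaks. Of 200 simulated lists per setting, with genes kept independently of each other, 100% of planted and 0.5% of unchanged lists were called. Permutation tests called 99% of shifted and 6% of unshifted sets in 100 runs, and within strata 100% and 4%. The software was python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, numba 0.67.0, pysam 0.24.0 and matplotlib 3.10.9.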

Results

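Peak lists from mouse embryonic stem cells were compared between wild-type E14 cells and cells homozygous for a gene trap in Mtf2. MTF2 is a Polycomb-like partner of Polycomb repressive complex 2 (PRC2), EZH2 is the catalytic subunit of PRC2, H3K27me3 is the histone mark that PRC2 lays down, and H3K4me3 marks promoters and is made by other enzymes. The series title names recruitment of PRC2 by MTF2 through DNA binding, and the comparisons address where MTF2 lies relative to PRC2 and which PRC2 sites are called without it. Each of the 7 lists stands for the 2 libraries of its group, so there is 1 list per group and no error between replicates. The depth of the libraries is unknown, since the lists hold positions without counts. Wild-type cells had 6357 MTF2, 7213 EZH2, 6294 H3K27me3 and 27418 H3K4me3 peaks, with median widths of 860, 775, 3631 and 1721 bp. Gene-trap cells had 840 EZH2, 963 H3K27me3 and 26960 H3K4me3 peaks, with median widths of 282, 3166 and 1547 bp. Promoters held 62.3% of MTF2 peaks, 60.1% of wild-type EZH2 peaks, 65.4% of wild-type H3K27me3 peaks and 49.6% of wild-type H3K4me3 peaks. In gene-trap cells they held 33.2% of EZH2, 62.1% of H3K27me3 and 50.9% of H3K4me3 peaks. The EZH2 share is not a move away from promoters, since 800 of the 840 gene-trap peaks lay inside 343 wild-type peaks. By wild-type peak, 211 of the 343 kept and 4121 of the 6870 lost EZH2 peaks were at promoters. All positions are on GRCm38.

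In wild-type cells MTF2 lay at the promoters of developmental regulators together with EZH2 and H3K27me3. Peaks covered all 41 Hox cluster genes and all 75 neural regulators, against 15.8% and 15.7% of other genes. The widest list members were Six3, a forebrain regulator, with an MTF2 peak of 19222 bp on chromosome 17 (85607452 to 85626673), Tbx2, a T-box factor of heart development, with 13583 bp, and Zic2 with 12347 bp. Of the 6357 MTF2 peaks, 93.7% (95% interval 93.1 to 94.3) overlapped an EZH2 peak, 95.4% (94.8 to 95.9) an H3K27me3 peak and 89.2% (88.4 to 89.9) an H3K4me3 peak. All 3 lists overlapped 5176 MTF2 peaks (81.4%), and 14 MTF2 peaks (0.220%) overlapped none of them. Seen from the other lists, an MTF2 peak overlapped 80.8% of EZH2, 68.5% of H3K27me3 and 18.3% of H3K4me3 peaks. Over 21827 promoters, the odds ratio of carrying MTF2 together with the mark was 1232 (1009 to 1505) for EZH2, 426 (357 to 510) for H3K27me3 and 49.2 (36.9 to 66.9) for H3K4me3.

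Of the 14 fixed lists, 11 had MTF2 at more of their promoters than other genes did. MTF2 marked 28 of 34 mesoderm and heart regulators (adjusted exact p = 6.02e-17), with Foxf1 (8380 bp) and Tbx1 (7867 bp) among the widest. It marked 14 of 19 endoderm regulators (adjusted exact p = 8.20e-08), including Lhx1 (8956 bp), Gata6 (8400 bp) and Gsc (5957 bp). Among signalling ligands and inhibitors 41 of 47 were marked (adjusted exact p = 3.08e-26), among them Gdf7 (5694 bp), Fgf9 (5407 bp) and Shh (5235 bp). Of the neuronal channels and receptors 39 of 46 were marked (adjusted exact p = 3.91e-24), such as Gad1 (4271 bp), which makes the transmitter GABA, Kcnk9 (4047 bp) and Kcna1 (3752 bp). In the Hox clusters (adjusted exact p = 1.17e-32) the widest peaks were at Hoxa9 and Hoxa10, which share 1 peak of 11778 bp, and at Hoxb5 (9185 bp). Neural regulators (adjusted exact p = 1.14e-59) also included Otx1 (11482 bp).

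The remaining lists had fewer MTF2 promoters. Imprinted genes had 13 of 26 (adjusted exact p = 0.000112, with Dio3 at 5316 bp, Igf2 at 4377 bp and Grb10 at 3494 bp). Extracellular matrix and epithelial genes had 12 of 31 (adjusted exact p = 0.00333, with Col2a1 at 4005 bp, Cdh2 at 3430 bp and Fbn1 at 2561 bp). PRC1 components had 9 of 21 (adjusted exact p = 0.00483, with Cbx8 at 2989 bp, Bcor at 2106 bp and Yaf2 at 2068 bp). Cell cycle inhibitors had 4 of 7 (adjusted exact p = 0.0189, with Cdkn1c at 2402 bp, Cdkn2a at 2227 bp and Cdkn2c at 1805 bp). Germline genes had 8 of 22 (adjusted exact p = 0.0189, with Dmrt1 at 1619 bp, Sycp1 at 865 bp and Ddx4 at 739 bp). None of the 30 housekeeping genes had an MTF2 peak, a lower share than in other genes (adjusted exact p = 0.0143). Pluripotency genes, with 3 of 29 (Esrrb at 2366 bp, Dnmt3b at 861 bp and Prdm14 at 508 bp, adjusted exact p = 0.658), and PRC2 and partners, with 1 of 13 (Phf19 at 1339 bp, adjusted exact p = 0.706), did not differ from other genes by this test. EZH2 was likewise higher in 10 lists, H3K27me3 in 11 and H3K4me3 in 11. With a promoter window of 2.5 kb, EZH2 no longer passed at extracellular matrix and epithelial genes (adjusted exact p = 0.0727). Nor did H3K4me3 at endoderm regulators (adjusted exact p = 0.0610).

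In Mtf2 gene-trap cells nearly all EZH2 peaks were gone from the list, and 286 of the 343 that stayed were in the widest of 5 equal classes of width. Of 7213 wild-type EZH2 peaks 343 were kept (4.76%, 4.28 to 5.27) and 6870 were lost, while 40 of the 840 gene-trap peaks were gained. The bases covered by EZH2 in gene-trap cells came to 3.78% of those in wild-type cells. Inside the 343 kept peaks lay 800 narrow gene-trap peaks, 2.33 per kept peak. Kept peaks had a median wild-type width of 3879 bp against 728 bp for lost peaks (log2 difference 2.41, permutation p = 1e-05, the smallest the resamples can give). A wider peak offers more bases for an overlap of 1 bp, so the rule for kept itself favours wide peaks. The permutation does not take this into account. Gene-trap peaks covered 20.5% of the wild-type length of the kept EZH2 peaks. In that widest class 19.8% of peaks were kept, and in the narrowest 0.833%. With peaks of at least 500 bp alone in both lists, 2.39% of EZH2 peaks were kept.

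**Figure D1:**
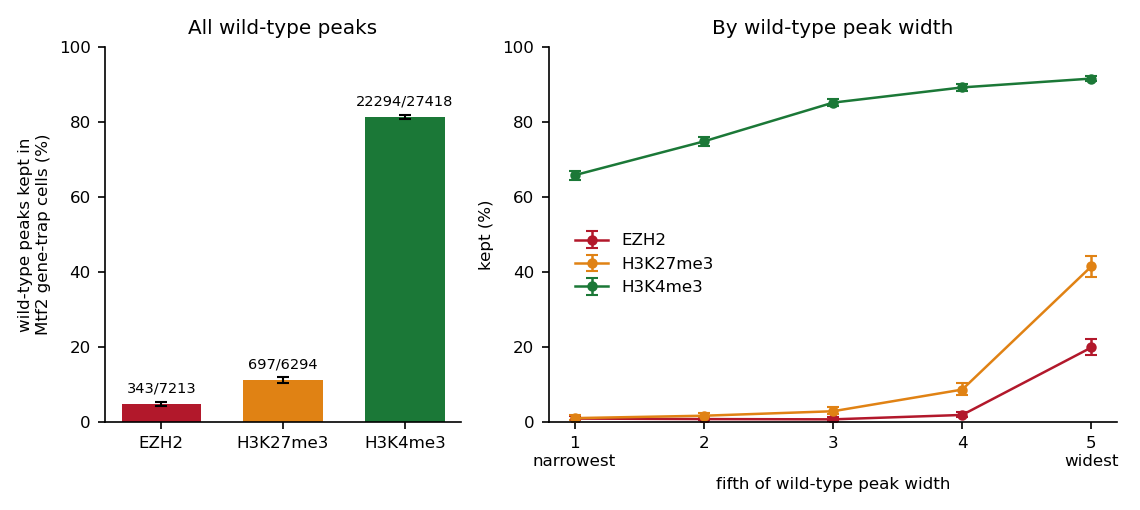
The left panel shows the percent of wild-type peaks of each mark overlapped by a gene-trap peak, with counts above the bars, and the right panel shows this percent in 5 equal classes of wild-type peak width from narrowest to widest. Error bars are 95% Clopper-Pearson intervals over peaks, and the share of EZH2 peaks kept is 0.833% in the narrowest, 0.623% in the middle and 19.8% in the widest class.

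Hox genes kept EZH2 most often among the fixed lists. For genes, a mark is lost when no gene-trap peak touches the promoter window, even if the wild-type peak that reaches it holds one elsewhere. A second width given for a gene is that of its widest gene-trap promoter peak, and the wild-type peak may hold others. At promoters, 154 of 3628 genes with a wild-type EZH2 peak still had one (4.24%, 3.61 to 4.95), and in the Hox clusters 28 of 41 did (68.3%, odds ratio 59.2, 28.7 to 127, adjusted exact p = 4.17e-29). The widest wild-type EZH2 peak spanned 34766 bp on chromosome 6 (52201965 to 52236730). It held 20 gene-trap peaks covering 8954 bp, among them peaks at Hoxa5 and Hoxa10 but none within 1 kb of a TSS of Hoxa3. Hoxa6, Hoxa7 and Hoxa9 share this wild-type peak too. The interval and p for the Hox clusters treat such genes as independent, which they are not. Hoxd10 had no gene-trap peak in its window either, although its wild-type peak of 8156 bp held 7 elsewhere. Neural regulators kept EZH2 at 30 of 75 genes (40%, odds ratio 18.4, 10.8 to 30.99, adjusted exact p = 3.79e-22). Six3 went from 19404 bp to a widest promoter peak of 1499 bp and Zic2 from 12378 to 443 bp, whereas Irx5 (10573 bp) and Irx3 (10313 bp) lost EZH2 at the window and held 3 and 2 gene-trap peaks elsewhere in the wild-type peak.

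Mesoderm and heart regulators kept 8 of 28 (28.6%, adjusted exact p = 5.30e-05). Tbx2 went from 13587 to 452 bp and Foxf1 from 9198 to 701 bp, while Gata2 (7808 bp), a blood regulator, and Foxc2 (6552 bp, with 1 gene-trap peak outside the window) lost EZH2. Endoderm regulators kept 4 of 14 (28.6%, adjusted exact p = 0.00672). Cdx2, a regulator of intestine and trophoblast, went from 9207 to 752 bp and Lhx1 from 9155 to 1016 bp, while Gata4 (6819 bp) and Gsc (6325 bp) lost it. PRC1 components kept 3 of 9 (33.3%, adjusted exact p = 0.0125), with Cbx8 going from 3254 to 264 bp. Bmi1, named after its values were seen, kept EZH2 too, and Bcor (2581 bp) and Pcgf5 (2096 bp) lost theirs. With genes compared within 5 classes of width, chosen after seeing the data, only the Hox and neural lists of these 5 were still called. The odds ratio went from 59.2 to 16.3 for Hox genes, from 18.4 to 4.05 for neural regulators, from 9.24 to 2.25 for endoderm regulators (the adjusted p was then 0.832) and from 9.46 to 2.46 for mesoderm and heart regulators (0.240). For PRC1 components it stayed near its value, 11.5 and 11.2, while the adjusted p rose to 0.158 with 3 of 9 genes kept. Under the other alternatives it went up to 0.0381, 0.00288 and 1. With the TSS itself inside the peak, 23.1% of Hox genes, 11.4% of neural, 16.0% of mesoderm and heart and 15.4% of endoderm regulators kept EZH2, all still called, and none of 5 PRC1 genes did.

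The other lists did not pass the test for EZH2. Signalling ligands and inhibitors kept 3 of 41 (7.32%, adjusted exact p = 0.431), Fgf9 (5584 to 1040 bp) and Gdf6 (4594 to 248 bp) among them, while Gdf7 (5652 bp) and Shh (5545 bp, with 1 peak outside the window) lost EZH2. With a promoter window of 2.5 kb this list kept 14.6% and was called (adjusted exact p = 0.0375), as it was with a gene-trap peak anywhere in the wild-type peak, chosen after seeing the data (adjusted exact p = 0.0435). Under the other 4 alternatives the adjusted p was from 0.413 to 1. Neuronal channels and receptors also kept 3 of 41 (7.32%, adjusted exact p = 0.431), Kcnk9 (4481 to 397 bp) and Gad1 (4077 to 297 bp) among them, while Gad2 (3890 bp, with 1 peak outside the window) and Kcna1 (3779 bp) lost theirs. Imprinted genes kept 1 of 13 (Igf2, 4724 to 173 bp, adjusted exact p = 0.647), and Dio3 (5388 bp) and Grb10 (3507 bp) lost EZH2. No member was kept among 4 cell cycle inhibitors (Cdkn1c 2433 bp and Cdkn2a 2392 bp), 3 pluripotency genes (Esrrb 2434 bp and Dnmt3b 722 bp) or 7 germline genes (Dmrt1 2114 bp and Sycp1 966 bp). None of 10 extracellular matrix and epithelial genes was kept either (Col2a1 4842 bp and Cdh2 3443 bp). The adjusted exact p was 1 for each of these 4 lists. PRC2 and partners and housekeeping genes had 2 wild-type EZH2 promoters each, kept none, and were too few to test.

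**Figure D2:**
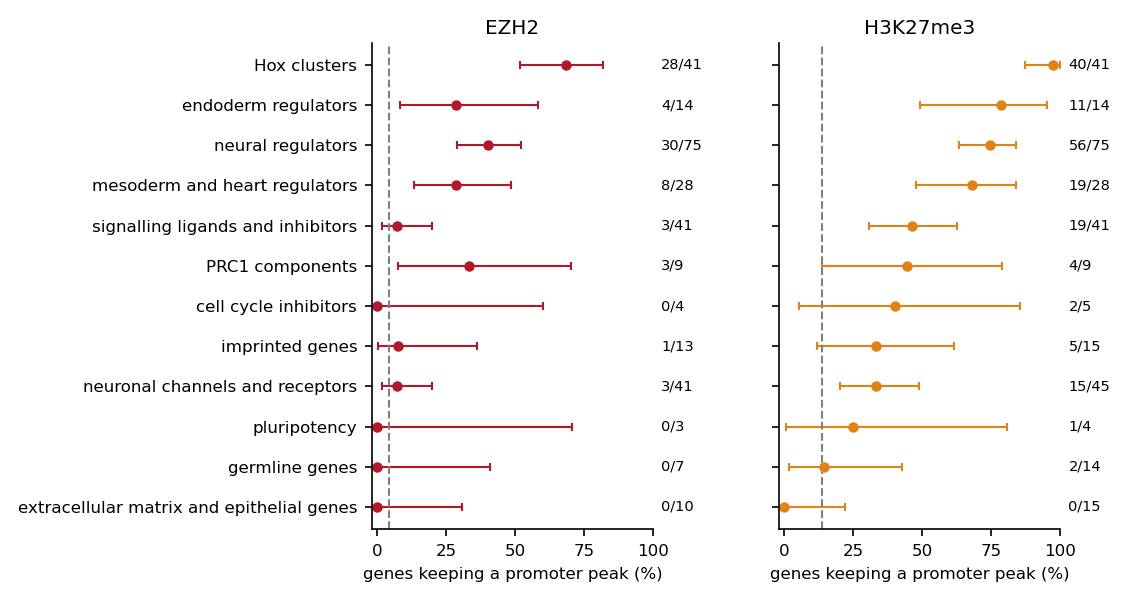
Points show the percent of genes in each fixed list that kept a promoter peak in gene-trap cells, for EZH2 on the left and H3K27me3 on the right, with kept and wild-type gene counts beside them. Bars are 95% Clopper-Pearson intervals, dashed lines mark all genes (4.24% and 13.7%), and Hox clusters lie highest at 68.3% and 97.6%.

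Outside the lists the widest kept EZH2 promoter peaks belonged to Ebf3 (14521 to 692 bp), Tfap2a (12764 to 975 bp), Sp9 (12039 to 1125 bp), Skor1 (10021 to 227 bp) and Nr2e1 (9813 to 914 bp). All 5 encode transcriptional regulators. The genes without EZH2 in the window that had the widest wild-type peaks were Dmrta2 (11980 bp), Mecom (9991 bp), Ebf2 (9149 bp), Msx1 (9063 bp) and Meis1 (7359 bp), which encode transcriptional regulators too. The peak at Dmrta2 still held 2 gene-trap peaks outside the window and that at Msx1 5, while the other 3 held none. EZH2 was gained at 6 promoters. Apart from predicted genes these were Coil (337 bp), Elobl (323 bp), Tbx3 (275 bp on chromosome 5, 119670509 to 119670783) and Tmem267 (154 bp).

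The Hox clusters lost most of their EZH2 coverage but little of their H3K27me3 coverage. In the HoxA region (chromosome 6, 52150590 to 52323378) EZH2 went from 99.6 to 17.5 kb covered, H3K27me3 from 149 to 130.1 kb and H3K4me3 from 44.2 to 46.2 kb. In HoxB (chromosome 11, 96189316 to 96373256) EZH2 went from 86.7 to 12.5 kb and H3K27me3 from 142 to 125.5 kb. In HoxC (chromosome 15, 102916103 to 103041852) EZH2 went from 72.1 to 12.6 kb and H3K27me3 from 123 to 111 kb. In HoxD (chromosome 2, 74647991 to 74770142) EZH2 went from 75.5 to 15.03 kb and H3K27me3 from 119 to 99.0 kb. H3K4me3 went from 32.6 to 37.8 kb in HoxB, from 39.1 to 29.3 kb in HoxC and from 21.8 to 31.7 kb in HoxD. These lengths depend on what was called in each list, and heights within a region are not in the lists.

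**Figure D3:**
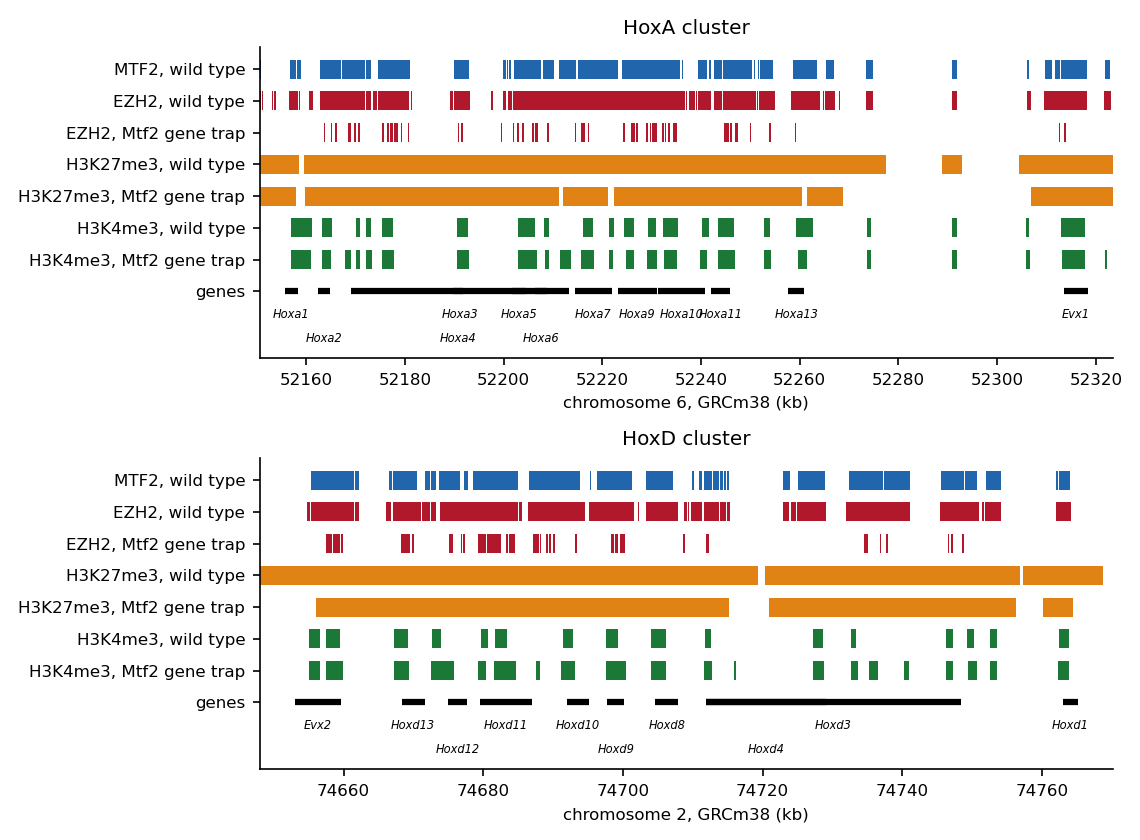
Boxes show the peaks of each list across the HoxA (top) and HoxD (bottom) regions, with the position in kb along the horizontal axis and protein-coding genes as black bars. In HoxA the EZH2 boxes cover 99.6 kb in wild-type and 17.5 kb in gene-trap cells, and the H3K27me3 boxes 149 and 130.1 kb.

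A larger share of H3K27me3 than of EZH2 peaks was kept, and 522 of the 697 kept peaks were in the widest of 5 classes of width. Of 6294 wild-type H3K27me3 peaks 697 were kept (11.1%, 10.3 to 11.9), 5597 were lost and 65 of the 963 gene-trap peaks were gained. Gene-trap H3K27me3 covered 15.9% of the wild-type length. Kept domains had a median wild-type width of 8948 bp against 3342 bp for lost ones (log2 difference 1.42, permutation p = 1e-05, the smallest possible). As for EZH2, the rule for kept itself favours wide peaks. In that class 41.5% were kept. Of the kept EZH2 peaks 93.6% overlapped a gene-trap H3K27me3 peak, and of the lost EZH2 peaks 17.9% did. Among 3420 genes with both marks in wild-type cells, 152 kept both, 412 kept H3K27me3 and lost EZH2, 2 kept EZH2 and lost H3K27me3, and 2854 lost both.

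At promoters 578 of 4206 genes kept H3K27me3 (13.7%, 12.7 to 14.8). As for EZH2, a second width is that of the widest gene-trap promoter peak, and a domain may hold more. In all, gene-trap peaks covered 18317 of 22693 bp of the domain at Wnt1 and 5108 of 28186 bp of that at Grb10. Hox clusters kept 40 of 41 (97.6%, odds ratio 270, 45.4 to 10917, adjusted exact p = 4.33e-33). Counting genes that share a peak once gave 9 of 10 (90%, odds ratio 61.6, adjusted exact p = 2.54e-07). The domain over Hoxb1 and Hoxb2 spanned 133253 bp and held 7 gene-trap peaks covering 109959 bp. Hoxc13 (13365 bp) was the gene without it in the window, although 1 gene-trap peak covered 11553 bp of its domain. That peak ended at 102920097 and the next began at 102922510, on either side of the gene start at 102921103. Endoderm regulators kept 11 of 14 (78.6%, adjusted exact p = 2.23e-07), with Foxa2 going from 25944 to 11167 bp and Foxa1 from 22467 to 6210 bp, while Cdx1 (6660 bp, with 1 peak outside the window) and Sox7 (6242 bp) lost it. Neural regulators kept 56 of 75 (74.7%, adjusted exact p = 6.92e-33). Zic1 and Zic4 share a domain of 39458 bp, with widest gene-trap promoter peaks of 6687 and 15877 bp, while Sox21 (19038 bp, with 1 peak outside the window) and Olig2 (18776 bp) lost H3K27me3. Mesoderm and heart regulators kept 19 of 28 (67.9%, adjusted exact p = 2.65e-10), such as Hand2 (45955 to 38140 bp) and Tbx15 (29684 to 3961 bp), while Twist1 (18663 bp) and Tbx18 (18402 bp, with 1 peak outside the window) lost it. Signalling ligands and inhibitors kept 19 of 41 (46.3%, adjusted exact p = 9.69e-07), such as Wnt1 (22693 to 9849 bp) and Wnt5a (19630 to 15792 bp), while Wnt3 (11904 bp, with 1 peak outside the window) and Bmp7 (10962 bp) lost it. With the TSS inside the peak the shares were lower, at 42.9% for endoderm, 43.7% for neural, 35.7% for mesoderm and heart regulators and 29.3% for signalling, all still called.

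Neuronal channels and receptors kept H3K27me3 at 15 of 45 genes (33.3%, adjusted exact p = 0.00126), such as Gad2 (13178 to 4425 bp) and Slc32a1 (10799 to 5363 bp), while Nrxn2 (7941 bp) and Grin2a (7255 bp) lost it. With the TSS inside the peak the share was 13.3% and the call ended (adjusted exact p = 0.463), while under the other alternatives the adjusted p lay between 0.000644 and 0.0318. PRC1 components kept 4 of 9 (44.4%, adjusted exact p = 0.0431), such as Bmi1 (35068 to 16195 bp) and Cbx8 (30021 to 11369 bp), while Bcor (18611 bp) and Pcgf5 (6638 bp) lost it. That call ended under 5 alternatives. The odds ratio was 5.05, and 4.77 with a window of 2.5 kb, where the share was the same and the adjusted p was 0.0509, and 1.78 with the TSS inside the peak, where it was 0.622. Imprinted genes kept 5 of 15 (33.3%, adjusted exact p = 0.0665), with Grb10 going from 28186 to 2923 bp and Igf2 from 16559 to 9947 bp, while Dlk1 (15713 bp) and Ascl2 (8537 bp) lost it. Counting genes that share a peak once gave 35.7% and a call for imprinted genes (adjusted exact p = 0.0393, up to 0.568 under other alternatives). Cell cycle inhibitors kept 2 of 5 (40%, adjusted exact p = 0.189). These were Cdkn2a (40881 to 1782 bp) and Cdkn1c (14154 to 5312 bp), while Cdkn2b (40881 bp, with 2 peaks outside the window) and Cdkn2c (14926 bp) lost it. Counting a gene-trap peak anywhere in the wild-type peak as kept, chosen after seeing the data, gave 60% and a call (adjusted exact p = 0.0494, up to 1 under other alternatives).

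Germline genes kept 2 of 14, Dmrt1 (7022 to 2304 bp) and Ddx4 (6014 to 1964 bp), while Tdrd1 (4234 bp) and Sycp2 (4061 bp) lost H3K27me3 (adjusted exact p = 1). Pluripotency genes kept 1 of 4, Esrrb (8793 to 3046 bp), while Dppa3 (13636 bp) and Dnmt3b (10579 bp) lost it (adjusted exact p = 0.487). None of 15 extracellular matrix and epithelial genes kept it (upper limit 21.8%, adjusted exact p = 0.298), Col2a1 (10789 bp, with 1 peak outside the window) and Cdh2 (8637 bp) being the widest. PRC2 and partners and housekeeping genes had 1 wild-type H3K27me3 promoter each and kept none. Outside the lists, the widest kept domains were at Nr2f2 (52159 to 9765 bp), Nfix (44192 to 21072 bp), Nr2f1 (43186 to 5785 bp) and Spag6 (35068 to 6238 bp). All gene-trap peaks in these domains together covered 45243, 29151, 14423 and 25112 bp, in the same order. The genes without H3K27me3 in the window that had the widest wild-type domains were Commd3 (35068 bp, the domain shared with Spag6 and Bmi1), Zic5 (33963 bp), Prickle1 (32604 bp), Cyp26c1 (21157 bp) and Tmem59l (20595 bp). All 5 domains still held gene-trap peaks elsewhere, from 3513 bp in that of Cyp26c1 to 25112 bp in that of Commd3. H3K27me3 was gained at 7 promoters, which apart from predicted genes were Coil and Elobl (1 peak of 3244 bp) and Pla2g12a (562 bp).

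H3K4me3 stayed at nearly all promoters. Of 14306 genes 14137 kept it (98.8%, 98.6 to 99.0), 169 lost it and 301 gained it. Over all peaks, 22294 of 27418 were kept (81.3%, 80.8 to 81.8) and 4472 of 26960 gene-trap peaks were gained. Kept peaks were wider in wild-type cells than lost ones (1876 against 1097.5 bp, log2 difference 0.77, permutation p = 1e-05, the smallest possible). Here too the rule for kept itself favours wide peaks. None of the 14 lists differed from other genes (adjusted exact p = 1 for each), and at least 95.8% of the members of each list kept H3K4me3. With 98.8% of all genes keeping it, no list could have been called higher by this test. The list members that lost it were Gria2 (482 bp), a glutamate receptor subunit, and Tagln (598 bp). Outside the lists the genes that lost it with the widest wild-type peaks were Zfp987 (8075 bp), Morc1 (5404 bp), Fam25c (4687 bp), Zfp626 (4450 bp) and Lst1 (4325 bp), and all but Morc1 and Fam25c had 1 gene-trap peak elsewhere in the wild-type peak. The widest gained ones were at Catsperg1 (5443 bp), Ubd (4845 bp), Rbbp8nl (4547 bp), Synpo2l (4097 bp) and Sh2d4b (3950 bp). The widest kept ones were at Jade1 (54044 to 17922 bp), Tet1 (45009 to 27025 bp), Trim71 (44042 to 22210 bp), and Gtsf1l and Mybl2, which share a wild-type peak of 40013 bp. A second width is again that of the widest gene-trap promoter peak. All gene-trap peaks together covered 25973 bp of the wild-type peak at Jade1, 25816 bp at Tet1 and 38898 bp at Trim71. Over all peaks, gene-trap H3K4me3 covered 81.8% of the wild-type length.

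The genes of PRC2 and its partners kept H3K4me3 at all 13 promoters. The widest H3K4me3 peak at the Jarid2 promoter was 68628 bp in wild-type and 20458 bp in gene-trap cells, and that at Mtf2 21320 and 3369 bp. All gene-trap peaks together covered 27452 bp of the wild-type peak at Jarid2 and 4185 bp of that at Mtf2. At Eed the widths were 14146 and 7869 bp, at Suz12 5641 and 4394 bp, at Ezh2 4242 and 3549 bp, at Phf1 1795 and 1328 bp and at Phf19 2392 and 2435 bp. No EZH2, H3K27me3 or MTF2 peak lay at the promoters of Mtf2, Ezh2, Eed, Suz12, Jarid2 or Phf1. Phf19, a Polycomb-like relative of Mtf2, had wild-type peaks of 548 bp for EZH2, 2381 bp for H3K27me3 and 1339 bp for MTF2, and no EZH2 or H3K27me3 peak in gene-trap cells. Pluripotency genes kept H3K4me3 at 28 of 28 promoters, with Esrrb going from 36617 to a widest promoter peak of 21479 bp and Zfp42 from 21983 to 4785 bp. In all, gene-trap peaks covered 32074 bp of the wild-type peak at Esrrb and 5894 bp of that at Zfp42. Of the extracellular matrix and epithelial genes 23 of 24 kept it, including the cadherin gene Cdh1 (20907 to 19967 bp).

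Promoters with both H3K4me3 and H3K27me3, often called bivalent, mostly went to H3K4me3 alone. Of 3984 such promoters in wild-type cells 3398 (85.3%) had H3K4me3 alone in gene-trap cells, 556 (13.96%) kept both and 30 had neither. In gene-trap cells 576 promoters had both marks. Marks were called at any TSS of a gene, so the 2 marks need not lie at the same TSS. H3K4me3 was kept at 99.1% of promoters that lost H3K27me3 and at all 556 that kept it (Fisher's exact test, p = 0.0164). With a window of 2.5 kb that difference no longer passed (exact p = 0.242). At promoters without wild-type H3K27me3 it was kept at 98.7% (odds ratio 1.55, 1.03 to 2.38, exact p = 0.0314).

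A smaller set of promoters with H3K27me3 alone gained H3K4me3. This happened at 78 of 222 (35.1%), against 223 of 7299 promoters with neither mark (3.06%, odds ratio 17.2, 12.5 to 23.5). Within 5 classes of CpG density at the TSS, a comparison chosen after seeing the data, the odds ratio was 6.70 (4.80 to 9.33). H3K27me3 was kept at 16 of the 78. List members among these 78 included Hoxa3 (2265 bp in gene-trap cells), Hoxb1 (1459 bp), Hoxb2 (3256 bp), Hoxb3 (2592 bp), Hoxd12 (3267 bp), Osr1 (1161 bp) and Zic4 (1940 bp). Gained list members were not in the naming rule as first written. All 7 genes named here kept H3K27me3, unlike most of the 78. At Hoxb2, Hoxb3 and Hoxd12 the gene-trap peak overlapped a wild-type H3K4me3 peak outside the window, so the gain there is not a new peak. At Hoxa3 and Hoxb1 it overlapped none.

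EZH2 and H3K27me3 were kept more often where MTF2 had been bound, but bound peaks were also wider. Of 5831 EZH2 peaks with MTF2 5.75% were kept, against 0.579% of 1382 without (odds ratio 10.5, 5.23 to 24.5, exact p = 3.67e-22). The median widths were 1006 and 256.5 bp. Within 3 equal classes of width the Mantel-Haenszel odds ratio was 2.04 (0.913 to 4.56). In the narrowest class bound peaks were kept more often (1.37% against 0.488%, odds ratio 2.83, 1.05 to 8.85), in the middle class the odds ratio was 0.485 (0.111 to 4.41), and the widest class, with most kept peaks, had only 5 unbound peaks. Of 4309 H3K27me3 peaks with MTF2 15.02% were kept, against 2.52% of 1985 without (odds ratio 6.84, 5.09 to 9.36, exact p = 4.76e-60). Within the 3 classes of width this odds ratio was 2.16 (1.56 to 3.00), from 0.683 (0.216 to 1.87) in the narrowest and 1.87 (0.942 to 4.11) in the middle to 2.81 (1.81 to 4.52) in the widest class, the only one whose interval excludes 1. For H3K4me3, 99.3% of peaks with MTF2 and 77.3% of those without were kept.

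MTF2 peaks were richer in CpG and GCG than H3K4me3 promoter peaks without MTF2. In the central 1 kb, 6357 MTF2 peaks had a median of 5.9 CpG and 4.4 GCG per 100 bp, against 4.4 and 2.8 in 10113 H3K4me3 promoter peaks without MTF2 (permutation p = 1e-05 for both, the smallest possible). Within 5 equal classes of CpG density GCG was still 0.39 per 100 bp higher (permutation p = 1e-05). Within 500 bp of the TSS of H3K4me3 promoters, chosen after seeing the data, the medians lay closer, at 6.5 and 6.1 for CpG and 5.0 and 4.2 for GCG, and GCG was 0.44 higher within classes of CpG density. Over whole peaks the differences were larger, 2.81 for CpG, 2.54 for GCG and 0.84 for GCG within classes of CpG density. With MTF2 peaks at promoters alone they were 2.5 for both CpG and GCG.

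Among EZH2 peaks, those with MTF2 had 6.0 CpG and 4.5 GCG per 100 bp and those without 3.4 and 2.2 (permutation p = 1e-05 for both). At equal CpG density GCG differed by 0.10 (permutation p = 0.025), which did not hold over whole peaks (0.026, permutation p = 0.55) or at promoters alone (0.080, permutation p = 0.14). In the central 1 kb, kept EZH2 peaks had less CpG than lost ones (4.4 against 5.7, permutation p = 1e-05) and less GCG (2.9 against 4.2, permutation p = 1e-05). At promoters alone the differences were -2.2 and -2.1. This direction depended on the window. In the densest 1 kb of each peak, an alternative chosen after seeing the data, kept peaks had more CpG by 1.2 (7.2 against 6.0, permutation p = 2e-05) and more GCG by 0.7 (5.1 against 4.4, permutation p = 0.0076). Kept peaks are wider, so the densest window is taken from more sequence in them. Within 5 classes of width kept peaks had less of both, here as differences between means and not medians. These classes were chosen after seeing the data, and for the densest 1 kb after seeing this reversal. The differences were -2.73 for CpG and -2.58 for GCG in the central 1 kb, and -1.35 and -1.40 in the densest 1 kb (permutation p = 1e-05 each). At equal CpG density, kept peaks differed in GCG by -0.20 in the central 1 kb (permutation p = 1e-05), by -0.37 at promoters alone and by -0.042 over whole peaks (permutation p = 0.39).

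**Figure D4:**
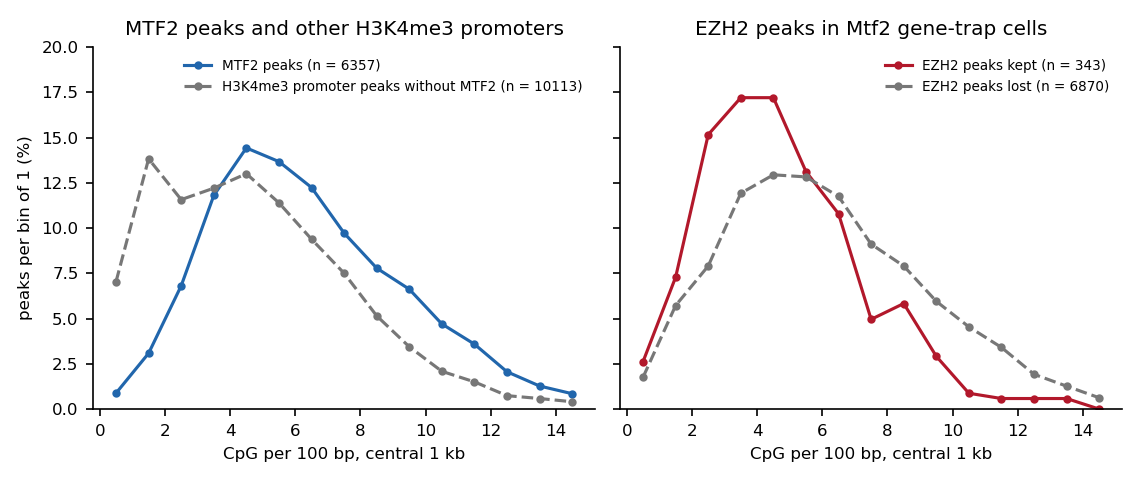
Lines show the percent of peaks in each bin of CpG per 100 bp of the central 1 kb, for MTF2 peaks and H3K4me3 promoter peaks without MTF2 on the left, and for kept and lost EZH2 peaks on the right. The medians are 5.9 and 4.4 on the left and 4.4 and 5.7 on the right, and in the densest 1 kb the order on the right turns to 7.2 and 6.0.

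No EZH2 peak on chromosome X was kept. A comparison of chromosomes, chosen after the values were seen, gave 0 of 168 on X (upper limit 2.17%) against 343 of 7045 on the autosomes (4.87%, odds ratio 0, 0 to 0.436, Fisher's exact test p = 0.00062). Single autosomes ranged from 1.37% on chromosome 10 to 7.28% on chromosome 2. For H3K27me3, 2 of 115 X-linked peaks were kept (1.74%) against 692 of 6176 autosomal ones (11.2%, odds ratio 0.140, 0.0167 to 0.521, Fisher's exact test p = 0.000249). The X-linked genes include the PRC1 gene Bcor, whose widest wild-type EZH2 promoter peak (12156924 to 12159504) was lost. Its widest H3K27me3 domain of 18611 bp lay apart from that peak (12075802 to 12094412) and was lost too. For H3K4me3, 651 of 767 X-linked peaks were kept (84.9%) and 81.2% of autosomal ones.

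**Figure D5:**
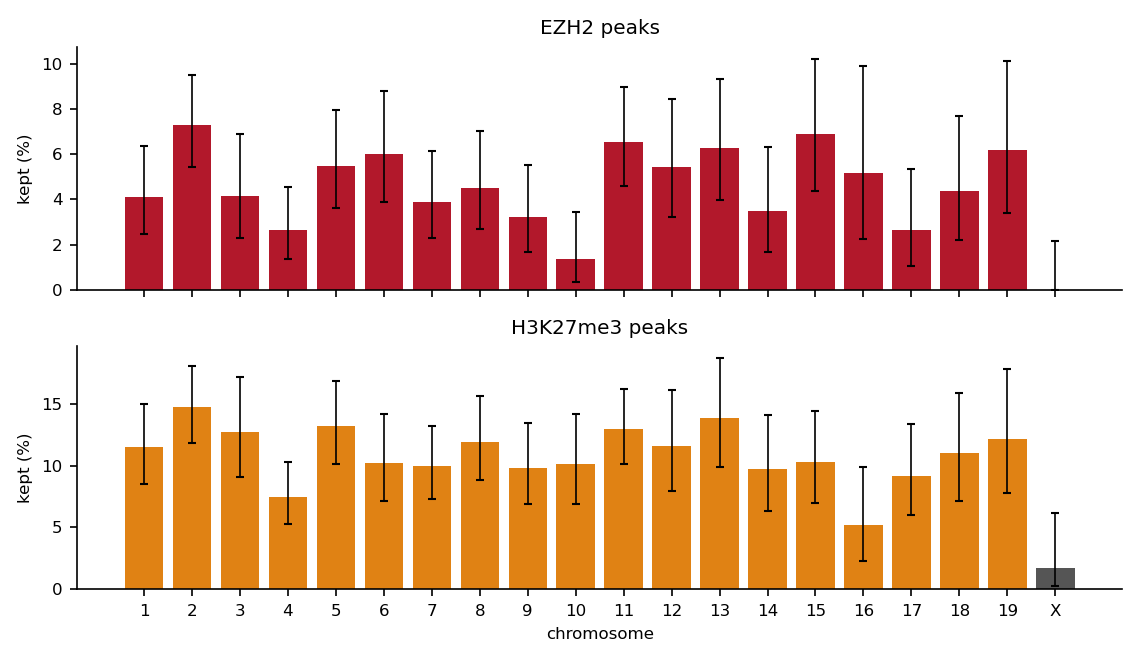
Bars show the percent of wild-type EZH2 (top) and H3K27me3 (bottom) peaks kept in gene-trap cells on each chromosome, with 95% Clopper-Pearson intervals. EZH2 has 0 of 168 peaks kept on X and H3K27me3 2 of 115, and the autosomes range from 1.37% to 7.28% for EZH2.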

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

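The settings that left out each chromosome, counted a mutant peak anywhere in the wild-type peak, compared lists within 5 classes of width, or used the densest 1 kb, 500 bp around the TSS or classes of CpG density were chosen after seeing the data, and the densest 1 kb within classes of width after seeing its reversal. No paired analysis was possible because there is 1 list for both libraries of each group, although the labels give the groups the same replicate numbers; for the same reason no replicate could be left out. A stricter threshold was not run, since the lists give no score per peak. Depth is unknown, so a lost peak cannot be told from a peak below the threshold. Of the main values under all alternatives, 123 kept their direction and their side of the threshold or moved within their interval, 18 moved, 5 lost their call and 2 reversed. Of the values for single lists 127 held, 9 lost a call, 4 gained one and 1 reversed. Leaving out chromosomes in turn gave odds ratios for MTF2-bound against unbound peaks from 9.50 to 13.3 for EZH2 and from 6.58 to 7.42 for H3K27me3.

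Overlap of MTF2 with EZH2 was 92.8% for 50% of the shorter peak, 95.9% within 1 kb and 95.5% for peaks of at least 500 bp. With H3K27me3 it was 95.9% within 1 kb and 98.5% for peaks of at least 500 bp, and with H3K4me3 88.2%, 93.1% and 93.4% under the 3 settings. EZH2 peaks kept were 6.56% within 1 kb, 2.39% at 500 bp or more and 3.60% as bases. As bases, H3K27me3 was kept at 15.2% and gained at 4.61%, and H3K4me3 at 69.8% and 14.7%. H3K4me3 peaks gained were 15.4% at 500 bp or more, and peaks kept 82.1% after merging. Wider tolerance adds overlaps by construction, and a share of bases leaves out the parts of kept peaks that no gene-trap peak covers. Otherwise the cause was not tested.

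Within 3 classes of width the odds ratio for EZH2 at MTF2-bound peaks was 2.04, and within 5 classes the lists called for EZH2 went from 5 to 2, with the odds ratio lower for Hox genes (59.2 and 16.3), neural (18.4 and 4.05), endoderm and mesoderm regulators but near its value for PRC1 components (11.5 and 11.2). With the TSS inside the peak, PRC1 components kept EZH2 at 0% (0 of 5 genes). With a window of 2.5 kb, H3K4me3 was kept at 99.4% of promoters that lost H3K27me3, and the difference from those that kept it no longer passed. Over whole peaks, GCG within classes of CpG density differed by -0.042 between kept and lost EZH2 peaks and by 0.026 between MTF2-bound and unbound ones, and the latter by 0.080 at promoters alone. In the densest 1 kb, kept minus lost EZH2 peaks reversed to 1.2 for CpG and 0.7 for GCG in medians. Within 5 classes of width that window gave differences in means of -1.35 and -1.40. For the other changes the cause was not tested.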

Other observations

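Among the tests in this part, the one of H3K4me3 recovery on X, the one of H3K4me3 length at lost against kept H3K27me3 and the ones of whether most gained regions or peaks are repeated were chosen after the results were seen, and the genes and regions named were chosen after their values were seen.

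Gained Polycomb regions were few, and several carried both EZH2 and H3K27me3. The 40 gained EZH2 peaks fell into 18 regions and the 61 gained H3K27me3 peaks on assembled chromosomes into 31, with 4 more on unplaced scaffolds. Around the promoters of Elobl and of Coil, which encodes the Cajal body protein coilin, 4 EZH2 peaks were gained between 88967863 and 88970689 on chromosome 11, together with an H3K27me3 peak of 3244 bp. H3K4me3 was wider there too. Its widest promoter peak went from 2698 to 3320 bp at Coil, and Elobl, without a wild-type H3K4me3 promoter peak, had 3320 bp. At Tmem267, with a gained EZH2 peak of 154 bp, H3K4me3 went from 1107 to 11271 bp. At Tbx3, a T-box gene of the pluripotency and mesoderm lists, 1 EZH2 peak of 275 bp was gained at the promoter and 3 H3K27me3 peaks lay near it, between 119662106 and 119673591 on chromosome 5 but none within 1 kb of a TSS, while the widest H3K4me3 peak at its promoter went from 21255 to 8064 bp. A gained EZH2 peak lay where the Mtf2 and Tmed5 genes overlap (chromosome 5, 108106687 to 108106920). Gains with both marks also lay on chromosome 17 from 13590378 to 13591122 and on chromosome 9 from 124256298 to 124257970.

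Of the 30 housekeeping genes, Hprt was the 1 without a wild-type H3K4me3 promoter peak, in a stretch of 136.5 kb without such a peak, and gene-trap cells had a peak of 2646 bp there (X, 52987646 to 52990291). E14TG2a, a subline of E14, is known to carry a deletion in Hprt, and the labels give neither the E14 subline nor the parental line of the gene-trap cells. This peak is therefore not read as a change in chromatin, and the other differences are not separated from line background either.

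No EZH2 peak on X was kept, against 4.87% on the autosomes. To test narrower peaks on X, autosomal peaks of matched width were drawn, and 0.076% of 100000 draws held no kept peak (median 6 kept). To test distance from list genes, draws were taken from autosomal peaks over 50 kb from any list TSS, of which 2.82% were kept. These width-matched draws held none in 0.571% (median 4), while 27 of the 168 X-linked peaks lay within 50 kb of a list TSS. Both shares are low, but the draws took single peaks as independent, and the 343 kept peaks fell into 192 regions. Such grouping makes draws without a kept peak too rare, by an amount not measured. Neither explanation is therefore excluded. Poor recovery of X in the gene-trap H3K4me3 libraries was argued against, since H3K4me3 was kept more often on X than on autosomes (odds ratio 1.30, 1.06 to 1.60). The EZH2 and H3K27me3 lists come from other libraries, which this test does not cover. No biological explanation was tested. Both H3K4me3 lists held peaks on chromosome Y, 24 in wild-type and 18 in gene-trap cells, and 11 of the wild-type ones were kept. Whether these Y-linked sequences are shared with other chromosomes was not tested, so the peaks do not settle the sex of the lines. Sex, strain and X copy number of the lines, as well as depth and calling, stay open.

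Some gained regions may come from reads shared between copies of a sequence. Regions made mostly of 75-base sequences found more than once were commoner among gained than lost regions, with an odds ratio of 15.3 (2.75 to 56.4) for EZH2 and 15.2 (2.79 to 53.3) for H3K27me3. They were few, at 3 of 18 (16.7%, 3.58 to 41.4) and 3 of 31 (9.68%, 2.04 to 25.8), which argues against sharing in most regions at a limit of 50% repeated. By single peaks at a lower limit it stays open, since regions over 40% repeated held 16 of 40 gained EZH2 peaks (40%, 24.9 to 56.7) and 26 of 61 gained H3K27me3 peaks (42.6%, 30.04 to 55.9). This depends on the lower limit. The regions over 50% repeated held 8, 1 and 1 gained EZH2 peaks and 1 gained H3K27me3 peak each. A gain of PRC2, differences between the lines in sequence or copy number, and differences in calling stay open and were not tested.

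H3K4me3 length within 10 kb of the most upstream TSS had a mean log2 ratio of gene-trap to wild-type of 0.01 at 3334 promoters that lost H3K27me3, -0.26 at 10107 that never had it and 0.11 at 549 that kept it. H3K27me3 was called at any TSS of the gene, so in genes with several TSSs the length may be measured away from it. In the first 2 sets the ratio went from 0.23 and 0.17 in the shortest of 10 classes of wild-type length to -0.34 and -0.56 in the longest, and the first set held 760 promoters in the shortest and 71 in the longest, so its mean joins gains and falls. Within such classes promoters that lost H3K27me3 lay 0.11 above those that never had it, but differed by -0.16 from those that kept it and lay below them in all 10 classes (permutation p = 1e-05 each, the smallest possible). If the loss of H3K27me3 as such were the cause, they were predicted to lie above those that kept it. This cannot decide the question, because promoters that kept it are no control without loss. Over all kept H3K27me3 peaks, gene-trap peaks covered 53.5% of the wild-type length. Starting length remains a candidate explanation for part of the first difference and cannot be told apart, since the 41.1% of it left after matching lies between the bounds set for and against it. What else sets promoters with wild-type H3K27me3 apart, and a difference in calling between the lists, were not tested.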
